A study of Apostichopus japonicus with 12 samples.

How the data were processed

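RNA from the intestine of the sea cucumber Apostichopus japonicus was measured in 12 libraries, 3 animals in each of 4 groups. These were animals kept at 18 °C, animals held at 26 °C for 6 h or 48 h, and animals held at 30 °C for 6 h. Per the labels' protocols, the water was warmed gradually and times were counted from the moment the target temperature was reached, so the 30 °C animals also went through a longer warming. Per the labels' protocols, RNA was taken from each animal separately with Trizol, messenger RNA was purified, libraries were made with TruSeq reagents, random hexamers and NEBNext adaptors, and they were sequenced on an Illumina HiSeq. The 3 libraries of a group are therefore separate animals. Groups and animal numbers were taken from the sample labels. Those labels gave the controls no time, and the same controls served the 6 h and the 48 h animals.

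The authors deposited a table of FPKM values (fragments per kilobase of gene, scaled by sequencing depth) for 30221 gene models, per the file headers, with a description, scaffold, start, end, strand and length for each. The aligner, the counting tool and the genome build were not given in the sources used here. A reference gene table was looked up by identifier, matched 0 of the identifiers and was not used, so names and positions are those of the deposited file and positions are on its scaffolds. Of the gene models, 94.04% have a length that is a multiple of 3, so the length is called the coding length. The file describes 13154 models as hypothetical or unnamed, and 4528 hold 0 in every library. The table held 0 value columns of other samples.

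The deposited FPKM values had already been scaled between libraries, which the values themselves show. Each FPKM multiplied by coding length was a whole multiple of a single step per library for 100% of values (tolerance 0.05 of a read), which gave back the number of reads on each gene. The divisors behind those steps were proportional to median-of-ratios size factors recomputed from the reads, with a constant of 2815402 in every library. The sum of FPKM per library ran from 562397 to 3014690. The recovered reads on genes came to 3109296, 2665272 and 3713358 in control animals 1 to 3, and to 2095221, 2299986 and 3627690 at 26 °C for 6 h. They came to 1788303, 2926724 and 2629072 at 26 °C for 48 h and 2661314, 3956056 and 3182338 at 30 °C. For a gene with no read in a group, 3 reads were used as the floor, which correspond to between 0.394 and 2.061 FPKM per library for a coding length of a kilobase. Lower bounds on folds ("at least") use a floor of 3 reads in each of the 3 libraries of the group. Intervals of shares of gene pairs are exact 95% intervals. Intervals of shares of reads are 95% Wilson intervals, those of ratios of reads are exact, and both, like the floors, cover counting error only, because reads made by amplification without molecular identifiers are not independent molecules.

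Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so a log2 change is on that scale and understates the change of low genes. The 18729 genes with a mean of at least 0.5 FPKM over the 12 libraries were kept, 11966 of them with a name. One model held a mean per group for all 12 libraries, with 8 residual and 5.652 prior degrees of freedom, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. The 5 comparisons were each heat group against control, 30 °C against 26 °C at 6 h, and 48 h against 6 h at 26 °C. An F test asked whether a gene differed among any of the 4 groups. Tests are two-sided.

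Gene lists were defined by words in the descriptions, before the data were examined, as were the groups, the tests, the alternatives first listed and the rule for named genes. Members whose description matched by accident were dropped afterwards from the descriptions alone. The 22 lists are cytosolic heat shock proteins, endoplasmic reticulum folding, mitochondrial chaperones and proteases, cytosolic chaperonin (CCT) subunits with prefoldin, and proteasome and ubiquitin. Others are antioxidant and glutathione enzymes, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, apoptosis, innate immunity, immediate early and stress transcription factors, and digestive enzymes. The rest are lipid metabolism, extracellular matrix, DNA replication and cell cycle, solute carriers and ABC transporters, mobile elements, markers of muscle, neurons and germ line, and histones. Each was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison. Camera with an estimated correlation and fry were alternatives. Of these fry asks a different question, whether the genes of a list changed in a common direction, without setting them against other genes. It also gives a test for change in either direction. Values of single libraries, such as the share of reads on a list, were compared with exact permutation tests, which with 3 animals against 3 cannot go below p = 0.1.

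The named gene rule took, per comparison with control, up to 6 rising and 6 falling genes with the largest log2 change among those past the threshold with a mean of at least 1 FPKM, a name and no overlap between groups. Between heat groups it took up to 4 and 4. It added the 2 members of each list with the largest change past the threshold, up to 30 genes in all per comparison, and the 5 heat shock proteins with the highest mean FPKM. Some names held by several gene models are given with their number of models, because reads of near-identical copies may have been split between them by the counting. Genes of this rule not so marked below are BSL78_17848 (5 models) and BSL78_28150 (3). The others are BSL78_20389, BSL78_05914, BSL78_00488, BSL78_05139 and BSL78_15659 (2 each).

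Alternatives first listed were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, values rescaled to a common sum in each library, and median-of-ratios or quantile scaling. Others first listed were the animal number as a block, a mean-variance trend with robust variances, array weights, a fit of only the groups compared, a log2 change of at least 1, and each library left out in turn. Added after the data were seen were voom on the recovered reads, a filter of at least 10 reads in at least 3 libraries, the number of genes detected as a covariate, a fit without the pair of libraries that stood farthest apart, and the list test on rescaled and on quantile-scaled values. Overlaps of calls that share the control animals were set beside 20 simulations of unchanged groups, in which the comparison of top-ranked genes was also added after the data were seen.

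The steps were tested on simulated data, made for the comparison of 30 °C with control on 18647 genes with 50 genes changed at each of 4 fold sizes. Of these, 0 of 50 were recovered at 2-fold and 0 of 50 at 4-fold. At 16-fold 15 of 50 were recovered, 11 of the 25 raised and 4 of the 25 lowered, and at 64-fold 28 of 50, 22 raised and 6 lowered. Of 46 genes called, 3 were not among those changed, and 0 genes were called in the unchanged comparisons. Each pair of libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom from 36.33 to 245.5, so none was counted as a duplicate. Correlations between libraries on the log2 scale, across genes, ran from 0.644 to 0.836, with a median of 0.745 within and 0.72 between groups. Sequence around the genes was not used here.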

Results

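The intestine of the sea cucumber Apostichopus japonicus, a bottom-dwelling echinoderm, was profiled at 18 °C (control), after 6 h and 48 h at 26 °C, and after 6 h at 30 °C, with 3 animals in each of the 4 groups. The values are the authors' FPKM, from which between 1788303 and 3956056 reads on genes per library were recovered, and 18729 gene models were tested with limma. Major yolk protein 2 (BSL78_17355), an iron-binding protein of the coelomic fluid and gonad of echinoderms, took 9.83% ± 7.12 (SD, n = 3) of the reads on genes in controls and 14.6% ± 4.17 after 6 h at 26 °C. It took 5.57% ± 3.63 after 48 h and 6.87% ± 2.82 at 30 °C. None of these shares was shown to differ from control (exact permutation p = 0.4, 0.5 and 0.6), and the control mean was 5.77% without control animal 1 and the 48 h mean 3.55% without 48 h animal 2. Ferritin (BSL78_19566), which stores iron, took 3.77% ± 0.671 in controls and 2.17% ± 0.515 at 30 °C. Its log2 change of 0.45 at 30 °C did not pass the test (adjusted p = 0.838). The share is of the reads of a library, whereas the FPKM values carry the deposited scaling, with sums per library from 562397 to 3014690, so the direction for ferritin depends on the scaling. With every library thinned to 1700000 reads, 16910 ± 1644 genes were detected in controls, 14666 ± 1993 after 6 h at 26 °C, 17784 ± 1630 after 48 h and 13894 ± 1236 at 30 °C (SD, n = 3 each). The exact permutation p against control was 0.2, 0.6 and 0.1, where 0.1 is the smallest p that 3 animals against 3 allow.

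The first question the design addresses is how the gut responds to heat, and cytosolic heat shock proteins gave the plainest answer. These are chaperones that bind unfolded proteins. Their list held 42 gene models, 37 of which were tested. All 42 together took 0.127% ± 0.0929 (SD, n = 3) of the reads on genes in controls and 3.30% ± 2.57 after 6 h at 26 °C. They took 0.528% ± 0.239 after 48 h at 26 °C and 22.99% ± 12.6 after 6 h at 30 °C. In single libraries the share at 30 °C was 23.5% (95% Wilson interval 23.5 to 23.6), 35.3% (35.3 to 35.3) and 10.2% (10.1 to 10.2). The highest control stood at 0.231% (0.226 to 0.236). Without that animal, control animal 3, the control mean was 0.0751%, and without 26 °C 6 h animal 3, at 6.22%, the mean of its group was 1.84%. In all 5 comparisons the values of the groups did not overlap, with an exact permutation p of 0.1 in each. Values of 3 animals against 3 fail to overlap by chance in 10% of cases.

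**Figure D1:**
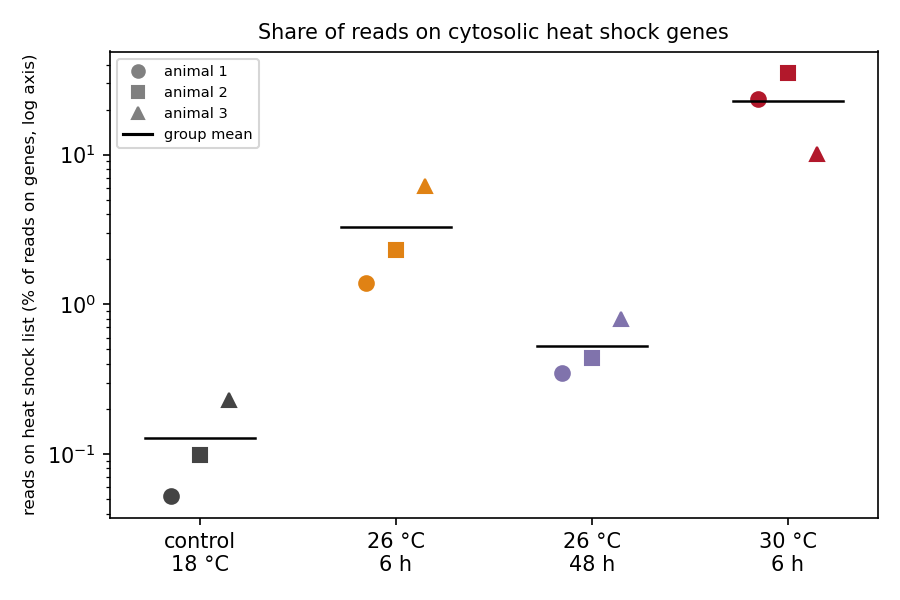
Share of the reads on genes that fell on the cytosolic heat shock list (percent, log axis) in the 4 groups, with a point per animal and a line at the mean of each group. Controls averaged 0.127% and the 30 °C animals 22.99%, with the 26 °C animals at 3.30% after 6 h and 0.528% after 48 h.

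After 6 h at 26 °C, 4 heat shock genes rose. Heat shock protein 70, the main inducible chaperone of animal cells, rose in its model BSL78_15519 (scaffold MRZV01000570.1, 221474 to 225378, coding length 1932). It went from 10.9 ± 11.4 to 3642 ± 3545 FPKM (SD, n = 3), a log2 change of 8.39 (SE 0.83, adjusted p = 0.000938). The HSP70 model BSL78_15518 on the same scaffold (197280 to 200838) rose by 6.81 (SE 1.06, adjusted p = 0.0461). The small heat shock protein HSP26 rose in BSL78_13662 (scaffold MRZV01000464.1, 241895 to 242536) by 7.52 (SE 1.09, adjusted p = 0.03), from 24.9 ± 26.5 to 4172 ± 4477 FPKM. It rose too in BSL78_21248 (scaffold MRZV01000980.1, 70357 to 71151) by 6.26 (SE 0.70, adjusted p = 0.00299). HSP70 has 7 gene models and HSP26 has 5, so the split of reads between the copies is uncertain.

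Across the 37 heat shock genes, 4 rose and 0 fell over all genes tested, and 25 rose and 0 fell adjusted over the list alone. Their mean log2 change was 3.46 (adjusted p = 5.37e-35 against other genes), but adjusted p = 0.125 with an estimated correlation. The sign of this mean was the same under every scaling tried. Models that missed the threshold over all genes included HSP26 BSL78_13663 (7.30, adjusted p = 0.0536) and HSP70 BSL78_02892 (7.16, adjusted p = 0.0666). Others were HSP26 BSL78_13664 (6.91, adjusted p = 0.0809), HSP26 BSL78_08844 (5.89, adjusted p = 0.0875) and heat shock protein 90-alpha 3 BSL78_26676 (5.35, adjusted p = 0.0516). HSP90 is the chaperone of kinases and hormone receptors. The count of 4 was 2 without control animal 1 or 2, 26 °C 6 h animal 2 or 3, or 48 h animal 3. It was 8, 7 and 12 without 26 °C 6 h animal 1, 30 °C animal 2 and 30 °C animal 3. It was also 2 with a pseudocount of 0.1, no filter, values rescaled to a common sum or the animal number as a block. It was 7 with voom, 8 with a mean of at least 5 FPKM, 9 with array weights and 14 with the number of genes detected as a covariate. Without both 26 °C 6 h animal 1 and 30 °C animal 3 it was 19.

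Outside that list, mitochondrial chaperonin Hsp56 (BSL78_09882, scaffold MRZV01000295.1, 621241 to 627617), part of the folding chamber of mitochondria, rose at 26 °C for 6 h from 90.9 ± 39.02 to 1104 ± 205 FPKM (log2 3.68, SE 0.61, adjusted p = 0.0496). A model named IMD-like protein (BSL78_12555, scaffold MRZV01000415.1, 60055 to 71869), after an adaptor of insect immune signalling, had 502 reads at 26 °C for 6 h and 0 in the control, 48 h and 30 °C animals. It stood at 110 ± 77.5 FPKM (72.8, 199 and 58.1 in the 3 animals), at least 79.2-fold higher than in controls (log2 6.58, SE 0.53, adjusted p = 0.000161), and it is 1 of 5 models of that name. The named genes that fell were heterogeneous nuclear ribonucleoprotein L (BSL78_06952, scaffold MRZV01000187.1, 215598 to 219356) and monocarboxylate transporter 6 (BSL78_15659, scaffold MRZV01000578.1, 509528 to 514457). The former regulates splicing and the latter is a membrane carrier. The ribonucleoprotein changed by -3.70 (SE 0.61, adjusted p = 0.0496), from 21.98 ± 1.38 to 0.899 ± 0.810 FPKM. The transporter changed by -3.17 (SE 0.50, adjusted p = 0.0496), from 13.8 ± 3.57 to 0.704 ± 0.612 FPKM.

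Of 3 other folding lists, 2 were shifted upward after 6 h at 26 °C. The third, 24 mitochondrial chaperones and proteases without Hsp56, averaged -0.39 with 8 of 24 above 0 and did not pass (adjusted p = 0.35). The cytosolic chaperonin list, 18 subunits of the CCT ring that folds actin and tubulin and of its helper prefoldin, had a mean log2 change of 1.24 (adjusted p = 5.67e-06, adjusted p = 0.349 with an estimated correlation). In it 0 genes rose over all genes and 8 adjusted over the list alone, all CCT ring subunits. Among them were T-complex protein 1 subunit beta BSL78_11119 (3.74, adjusted p = 0.13) and delta BSL78_14696 (2.56, adjusted p = 0.295). The 22 genes of endoplasmic reticulum folding averaged 0.71 (adjusted p = 0.00128, adjusted p = 0.351 with an estimated correlation), 2 of them risen adjusted over the list alone and 0 over all genes. The 78 kDa glucose-regulated protein (BSL78_16330), the main chaperone of that compartment, stood at 736 FPKM against 64.1 (log2 3.62, adjusted p = 0.177). Going the other way, 42 muscle markers averaged -0.69 (adjusted p = 0.000389, adjusted p = 0.611 with an estimated correlation), with 6 of 42 above 0. The 54 genes of DNA replication and cell cycle averaged -0.47 (adjusted p = 0.0343, adjusted p = 0.666 with an estimated correlation). In both lists 0 genes were called, over all genes or adjusted over the list alone. The muscle list holds filamin-B (BSL78_10927, -0.33, adjusted p = 0.922) and myosin regulatory light chain 12A (BSL78_07616, -0.30, adjusted p = 0.952), which other cells also express. In the same animals the number of genes detected was lower (14666 against 16910). The DNA replication call was lost without control animal 2 (adjusted p = 0.175) or 26 °C 6 h animals 1 (0.279) or 2 (0.154), and with quantile scaling (0.159).

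In all, 9 genes rose and 3 fell after 6 h at 26 °C by limma (1510 at an unadjusted p under 0.05, with 936 due by chance), 6 and 2 of them named. The third that fell is hypothetical (BSL78_11524, log2 -4.01, adjusted p = 0.0496), named after its values were seen because it completes the count. HSP70 BSL78_15519, HSP26 BSL78_21248 and IMD-like BSL78_12555 passed under every alternative, whereas the other 5 lost their call in at least 1 fit with a library left out. Of the 8 named calls, 5 were lost without control animal 1 (adjusted p from 0.101 to 0.207) or 2 (0.0728 to 0.131), and 4 without control animal 3 (0.0542 to 0.097). Another 3, 5 and 5 were lost without 26 °C 6 h animals 1 (0.0597 to 0.0711), 2 (0.0891 to 0.163) and 3 (0.103 to 0.131). Through the shared spread, 3, 4 and 5 were lost without 48 h animals 1 (0.0648 to 0.0756), 2 (0.0697 to 0.0833) and 3 (0.06 to 0.0953). The same held for 4 without 30 °C animal 1 (0.0715 to 0.0749). The size of 3 of the 8 moved by over 1.5 times with a library left out, at most by 1.18 on the log2 scale (HSP26 BSL78_13662, 6.34 without control animal 1). The 12 calls became 5, 6 and 5 without control animals 1, 2 and 3, and 7 and 4 without 26 °C 6 h animals 2 and 3. They became 6, 5 and 4 without 48 h animals 1, 2 and 3, and 37 without 30 °C animal 3. Without both that animal and 26 °C 6 h animal 1, a pair picked after the data were seen by no distance rule, they became 66.

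After 48 h at 26 °C the same heat shock genes stood closer to control. HSP26 BSL78_13662 was at 246 ± 177 FPKM against 24.9 ± 26.5 in controls (SD, n = 3; log2 3.75, SE 1.09, adjusted p = 0.866). HSP26 BSL78_13663 was at 151 ± 172 against 8.59 ± 11.3 (log2 4.21, SE 1.23, adjusted p = 0.866). HSP70 BSL78_02892 stood at 3.42 (SE 1.33), HSP26 BSL78_13664 at 2.92 (SE 1.33) and HSP26 BSL78_08844 at 2.87 (SE 1.17), each with adjusted p = 1. As a list the 37 heat shock genes still averaged 1.498 above control (adjusted p = 1.99e-11, adjusted p = 0.734 with an estimated correlation), a sign kept under every scaling. In it 0 were called over all genes and 4 had risen adjusted over the list alone. Endoplasmic reticulum folding averaged 0.55 (adjusted p = 0.0304, adjusted p = 0.751 with an estimated correlation; 1 gene risen adjusted over the list alone).

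Of single genes, limma called 0 after 48 h at 26 °C (852 at an unadjusted p under 0.05, with 936 due by chance; smallest adjusted p = 0.343), and voom on the recovered reads called 0. Solute carriers, 345 membrane transporters, averaged -0.29 (adjusted p = 0.0304, adjusted p = 0.751 with an estimated correlation) and 87 ribosomal proteins -0.27 (adjusted p = 0.0496, adjusted p = 0.926 with an estimated correlation). In both lists 0 genes were called, over all genes or adjusted over the list alone. The ribosomal call was lost without control animal 2 (adjusted p = 0.549), 26 °C 6 h animal 1 (0.0556), 48 h animal 2 (0.799) or 30 °C animals 1 (0.0559) or 2 (0.0571). It turned upward without control animal 1 (0.192) or 48 h animal 3 (0.747). With values rescaled to a common sum both the ribosomal and the endoplasmic reticulum call were lost (adjusted p = 0.112 for each), and with quantile scaling the ribosomal call (0.844). The solute carrier call was lost without control animal 3 (0.212) or 48 h animal 1 (0.177). The endoplasmic reticulum call was lost without control animals 1 (0.178) or 2 (0.15), 48 h animal 3 (0.114) or 30 °C animal 2 (0.0571). A single gene was called without control animal 1 and a single gene without 48 h animal 3, where the full set gave 0.

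At 30 °C for 6 h, HSP26 and HSP70 became some of the most read genes of the gut. HSP26 BSL78_13662 went from 24.9 ± 26.5 to 133567 ± 78329 FPKM (SD, n = 3), 4.81% ± 2.82 of all reads on genes, a log2 change of 13.01 (SE 1.09, adjusted p = 0.000118). Its neighbours BSL78_13663 (243745 to 244446) and BSL78_13664 (247457 to 248005) on scaffold MRZV01000464.1 rose by 13.90 (SE 1.23, adjusted p = 0.00013) and 13.07 (SE 1.33, adjusted p = 0.00037). HSP26 BSL78_08844 (scaffold MRZV01000256.1, 441916 to 442593) rose by 12.86 (SE 1.17, adjusted p = 0.00013). Among HSP70 models on scaffold MRZV01000064.1, BSL78_02917 (840013 to 843645) rose from 6.65 ± 9.06 to 31158 ± 5987 FPKM, by 12.76 (SE 1.15, adjusted p = 0.00013). BSL78_02892 (270577 to 270996) rose by 12.24 (SE 1.33, adjusted p = 0.000567).

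**Figure D2:**
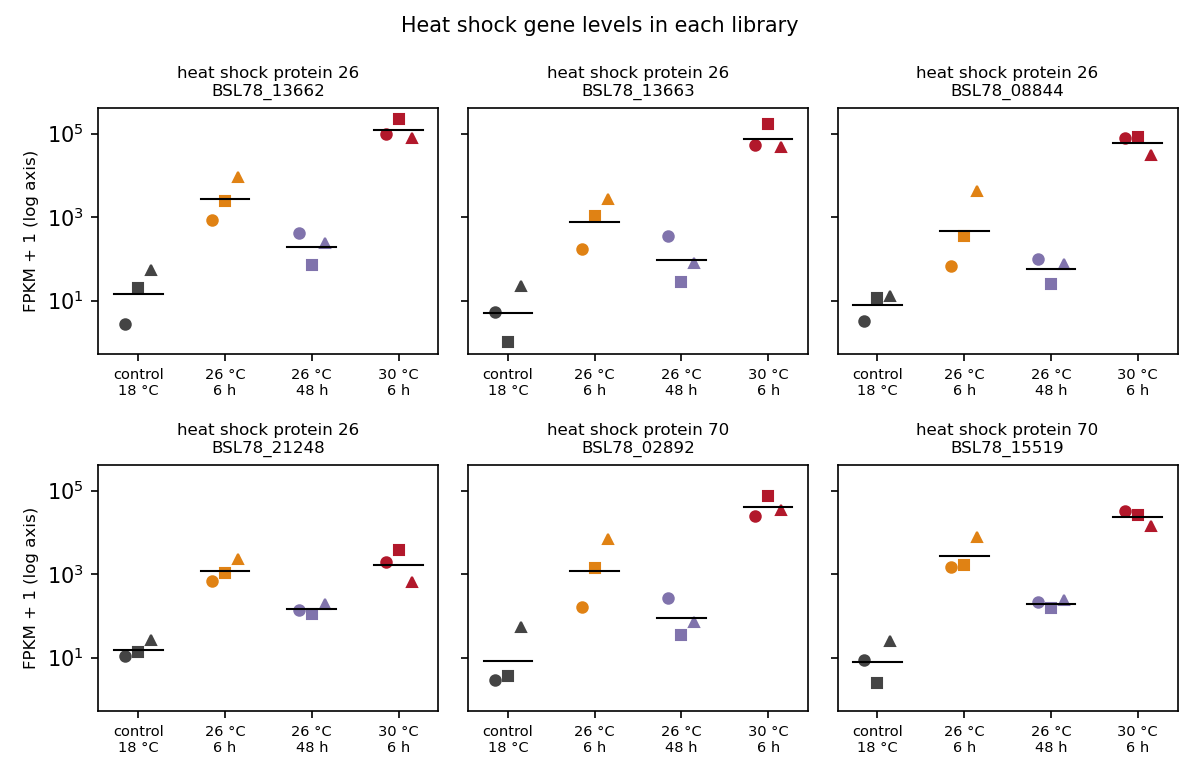
FPKM + 1 (log axis) of 4 models of HSP26 and 2 of HSP70 in the 4 groups, with a point per animal and a line at the mean on the log scale. In every panel the mean at 30 °C is the highest of the 4 groups, HSP26 BSL78_13662 averaging 133567 FPKM there, 4172 after 6 h at 26 °C, 246 after 48 h at 26 °C and 24.9 in controls.

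Of the 37 heat shock genes, 20 rose and 0 fell at 30 °C, by log2 2.97 to 13.90, and adjusted over the list alone 27 rose and 1 fell. The mean of the list was 5.41 (adjusted p = 4.24e-43, adjusted p = 0.0697 with an estimated correlation), and 4.27 with values rescaled to a common sum. That rescaling left 12 risen genes, and a fit of only the groups compared 13. Besides HSP26 and HSP70 the risen genes included HSP90-alpha 3 (BSL78_26676, 6.14, adjusted p = 0.00495) and its helpers, stress-induced phosphoprotein 1 (BSL78_07970, 5.51, adjusted p = 0.0091) and the activator of HSP90 ATPase (BSL78_20250, 5.28, adjusted p = 0.00783). BAG3 (BSL78_05946), a partner of HSP70 in clearing damaged protein, rose from 1.45 ± 1.85 to 2056 ± 871 FPKM (log2 9.89, adjusted p = 0.000401). Alpha-crystallin B (BSL78_12794) rose by 2.97 (adjusted p = 0.036). The 11 models of heat shock cognate 70, the constitutive form, had 0 calls over all genes at 30 °C and log2 changes from -2.95 to 2.94. Adjusted over the list alone 5 of them rose and 1 fell, and whether they differed from the inducible genes was not tested.

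Among other lists at 30 °C, the chaperonin list averaged 1.25 (adjusted p = 9.18e-05, adjusted p = 0.34 with an estimated correlation), a mean of 0.14 with values rescaled to a common sum. That rescaling moved the median of all genes by -0.68, to -0.76, and the list stayed 0.90 above it (adjusted p = 0.00168). In it 1 gene rose over all genes and 6 adjusted over the list alone. T-complex protein 1 subunit delta (BSL78_14696, scaffold MRZV01000522.1, 325637 to 335186) rose from 54.7 ± 20.3 to 661 ± 539 FPKM (log2 3.32, SE 0.69, adjusted p = 0.0452). Prefoldin subunits ran from -1.43 (BSL78_24609) to 1.52 (BSL78_21557). Of 129 digestive enzymes, alpha-amylase 4N (BSL78_20389, scaffold MRZV01000906.1, 203276 to 209053), which cleaves starch, rose from 0.260 ± 0.450 to 58.4 ± 52.6 FPKM (log2 5.12, SE 0.79, adjusted p = 0.00742). Of 189 extracellular matrix genes, metalloproteinase inhibitor 1-like (BSL78_28150, scaffold MRZV01002005.1, 24747 to 28385) rose from 17.8 ± 0.284 to 129 ± 33.6 FPKM (log2 2.75, SE 0.54, adjusted p = 0.034). Of 195 lipid metabolism genes, fatty acid-binding protein type 3-like (BSL78_24333, scaffold MRZV01001309.1, 193700 to 194080) rose from 6.53 ± 11.3 to 1073 ± 1274 FPKM (log2 7.06, SE 1.46, adjusted p = 0.0452), and it has 3 models of its name.

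The mobile element list, 84 models, averaged 0.04 (adjusted p = 0.977) and held 2 risen genes over all genes and 3 adjusted over the list alone. A retrovirus-related Pol polyprotein (BSL78_18574, scaffold MRZV01000769.1, 330396 to 331613, 1 of 10 models) was at 120 ± 106 FPKM against 0 reads in controls. It was at least 183-fold higher (log2 5.97, SE 0.92, adjusted p = 0.00742). A model described as starfish testis sperm peptide transposon (BSL78_10877, scaffold MRZV01000337.1, 587808 to 588104) was at 123.1 ± 120.2 FPKM and at least 45.9-fold higher (log2 6.05, SE 0.92, adjusted p = 0.00668). The second is also the 1 gene risen among 71 germ line markers, which averaged -0.09 (adjusted p = 0.506).

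The named genes that fell at 30 °C include a pair of carrier models. Monocarboxylate transporter 6 fell in BSL78_15659, from 13.8 ± 3.57 FPKM to 0 reads, at least 9.33-fold lower (log2 -3.86, SE 0.50, adjusted p = 0.00232). Its neighbour BSL78_15660 (514691 to 515698, isoform X2) fell from 29.9 ± 7.58 to 1.48 ± 2.56 FPKM (log2 -4.11, SE 0.79, adjusted p = 0.0325; 185 reads against 3, a ratio of 24.1, counting interval 8.13 to 118). Both belong to the solute carrier list, which averaged -0.21 (adjusted p = 0.241) with 2 genes fallen over all genes and 3 adjusted over the list alone. Named as isoforms X1 and X2 of the same transporter, the neighbours may not be separate genes, which was not tested. Galactosylceramide sulfotransferase (BSL78_21866, scaffold MRZV01001033.1, 223959 to 224663, 1 of 21 models), which makes sulfated membrane lipids, fell from 32.4 ± 12.4 FPKM, 280 reads, to 1 read (log2 -4.71, SE 0.63, adjusted p = 0.00285; ratio 110, counting interval 19.5 to 4340). AP-3 complex subunit sigma-1 (BSL78_01882, scaffold MRZV01000039.1, 103678 to 112307), of vesicle traffic, fell from 8.18 ± 0.0702 FPKM to 0 reads, at least 1.61-fold lower (adjusted p = 0.0283). Ankyrin repeat protein 13C-A-like (BSL78_00485, scaffold MRZV01000009.1, 835063 to 837467) fell to 0 reads too, at least 1.82-fold lower (adjusted p = 0.0106). The ciliary protein rib74 (BSL78_05139, scaffold MRZV01000128.1, 219518 to 223922) fell from 9.21 ± 2.16 to 0.579 ± 0.529 FPKM (log2 -2.73, SE 0.54, adjusted p = 0.035).

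Besides heat shock proteins and chaperonin, 7 lists passed the preset-correlation test upward at 30 °C. All 7 means fell below 0 with values rescaled to a common sum, but so did the median of all genes, so rescaled means are given relative to that median, with the adjusted p of the same test. Ribosomal proteins averaged 0.97, with 76 of 87 above 0 (adjusted p = 2.94e-10, adjusted p = 0.516 with an estimated correlation), 0.47 above the median rescaled (0.0127) but -0.18 from it with quantile scaling (0.0991). Oxidative phosphorylation, 70 genes of the respiratory chain, averaged 0.36 (adjusted p = 0.00166, adjusted p = 0.516 with an estimated correlation), but went the other way relative to the median, -0.10 rescaled (0.415) and -0.29 with quantile scaling (0.0991). Extracellular matrix averaged 0.56 (adjusted p = 0.000105, adjusted p = 0.34 with an estimated correlation; 1 gene risen over all genes, 2 adjusted over the list alone), and 0.54 relative to the median rescaled (0.000101). Digestive enzymes averaged 0.61 (adjusted p = 0.0051, adjusted p = 0.516 with an estimated correlation; 1 risen over all genes, 2 adjusted over the list alone), and 0.51 rescaled (0.0127), but the call was lost with quantile scaling (0.0538). Innate immunity, 181 genes, averaged 0.44 (adjusted p = 0.0118, adjusted p = 0.34 with an estimated correlation), and 0.40 rescaled (0.00218), but the call was lost with quantile scaling (0.0538). Antioxidant and glutathione enzymes, 83 genes, averaged 0.31 (adjusted p = 0.0399, adjusted p = 0.475 with an estimated correlation), and 0.12 rescaled (0.368), where the call was lost, as with quantile scaling (0.409). Neuron markers, 104 genes, averaged 0.58 (adjusted p = 0.000894, adjusted p = 0.516 with an estimated correlation), and 0.70 rescaled (4.87e-05). Their largest values were those of acetylcholinesterase models BSL78_07501 (3.998, adjusted p = 0.546) and BSL78_15351 (2.96, adjusted p = 0.363). Of ribosomal, respiratory, immune, antioxidant and neuron genes 0 were called, over all genes or adjusted over the list alone.

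Some of these list calls rested on single animals. Oxidative phosphorylation lost its call without control animal 3 (adjusted p = 0.227) or 30 °C animal 3 (0.153). Innate immunity lost it without control animals 1 (0.052) or 2 (0.0582) or 30 °C animal 3 (0.149). Antioxidant enzymes lost theirs without control animals 2 (0.0582) or 3 (0.107) or 30 °C animals 1 (0.0503) or 3 (0.177). Digestive enzymes (0.0573) and neuron markers (0.0922) lost theirs without 30 °C animal 2.

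The remaining lists at 30 °C did not pass. Immediate early and stress transcription factors, 14 genes of which some are switched on within minutes of a stimulus, averaged 0.75 (adjusted p = 0.066, 4 risen adjusted over the list alone and 0 over all genes). With values rescaled to a common sum they stayed 0.53 above the median of all genes (0.197). Made by names, the list lacks a Klf transcription factor that rose, which is given under the other observations. Fos-related antigen 1 (BSL78_02081) stood at 1863 FPKM against 71.5 (log2 4.38, adjusted p = 0.0591) and early growth response 1-B (BSL78_08425) at 2.51 (adjusted p = 0.268). Endoplasmic reticulum folding averaged 0.40 (adjusted p = 0.168), 22 genes of glycolysis 0.29 (0.241), 10 histones 0.39 (0.28), lipid metabolism 0.24 (0.349) and 24 mitochondrial chaperones and proteases 0.09 (0.693). Apoptosis, 75 genes, averaged -0.16 (0.419), DNA replication -0.12 (0.693), 77 genes of proteasome and ubiquitin -0.03 (0.977) and muscle markers -0.05 (0.977). Rescaled to a common sum, proteasome and ubiquitin passed downward, -0.28 from the median of all genes (0.0173), and mobile elements upward, 0.42 above it (0.0166).

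**Figure D3:**
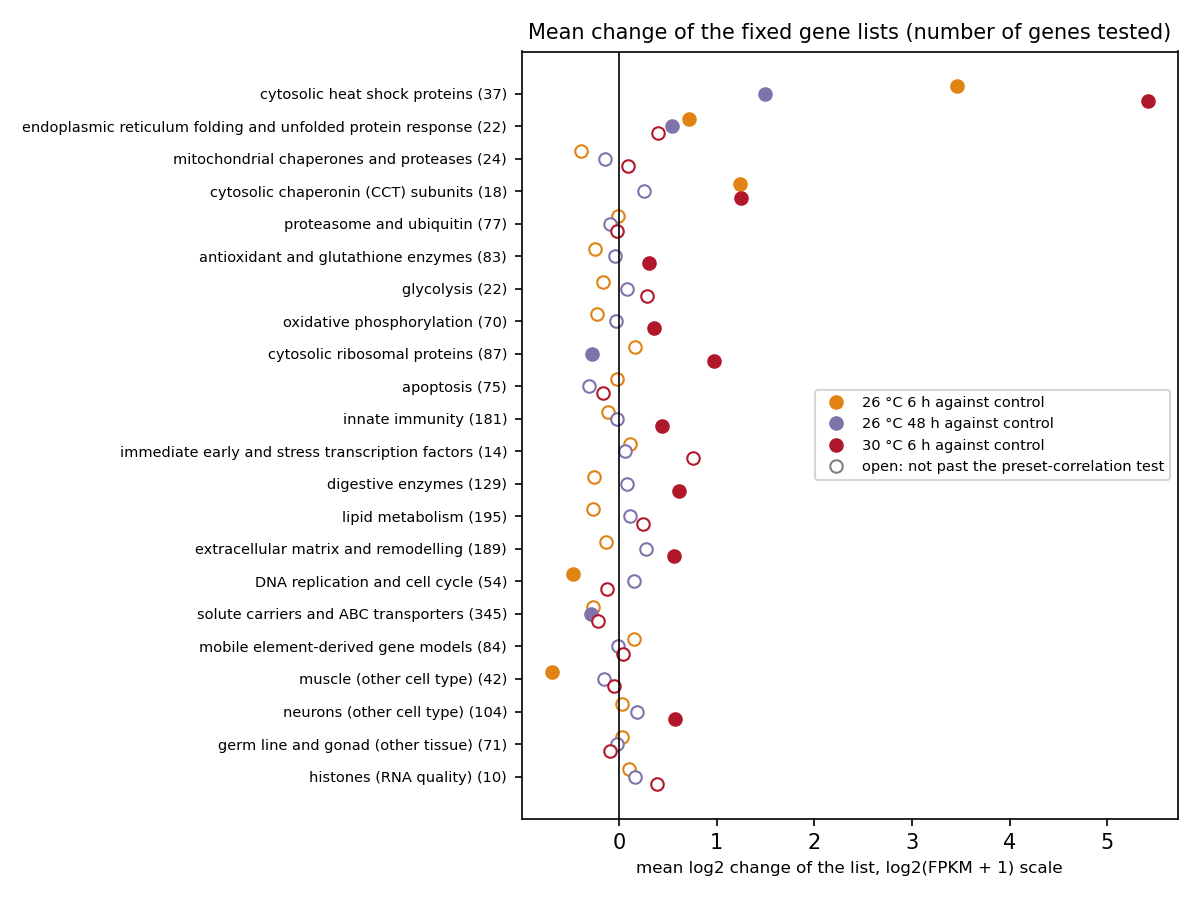
Mean log2 change against control (horizontal axis) of the 22 gene lists (vertical axis) in the 3 heat groups, filled where the preset-correlation test was passed and open where it was not. Heat shock proteins stand apart at 3.46, 1.498 and 5.41, and of the other lists filled at 30 °C oxidative phosphorylation lies below the median of all genes when values are rescaled to a common sum (-0.10), and with ribosomal proteins also under quantile scaling (-0.29 and -0.18).

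In all, 110 genes rose and 12 fell at 30 °C by limma (1942 at an unadjusted p under 0.05), 58 and 7 of them named. Of the risen, 52 are hypothetical and 26 belong to a list. Of the risen, 23 had no read in controls, and 4 of the fallen had none at 30 °C. Rescaled to a common sum, 31 rose and 20 fell, so that 60.8% of calls rose in place of 90.2%. The 8 genes BSL78_02892, BSL78_02917, BSL78_08844, BSL78_13662, BSL78_13663, BSL78_13664, BSL78_15659 and BSL78_21866 passed under every alternative. Of the 18 named calls, 6 each were lost without control animals 1 (adjusted p from 0.0933 to 0.17), 2 (0.054 to 0.103) and 3 (0.0894 to 0.167). Another 7 each were lost without 30 °C animals 1 (0.0549 to 0.178) and 2 (0.0522 to 0.181), and 1 without animal 3 (0.0537). Through the shared spread, 1, 3 and 1 were lost without 26 °C 6 h animals 1 (0.0607), 2 (0.0508 to 0.0643) and 3 (0.0558). The same held for 4 each without 48 h animals 1 (0.0506 to 0.0665), 2 (0.0538 to 0.0718) and 3 (0.0514 to 0.0711). The size of 12 of the 18 moved by over 1.5 times with a library left out, at most by 1.85 on the log2 scale (fatty acid-binding protein BSL78_24333, 8.92 without 30 °C animal 3 and 5.68 without animal 1). The 122 calls became 59, 77 and 75 without control animals 1, 2 and 3. They became 52, 54 and 258 without 30 °C animals 1, 2 and 3. Animal 3 at 30 °C stood apart from its group on the second principal component, and without it and 26 °C 6 h animal 1 there were 281.

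Genes called at both 26 °C and 30 °C after 6 h numbered 6. HSP26 BSL78_13662 and BSL78_21248, HSP70 BSL78_15519 and BSL78_15518 and mitochondrial chaperonin Hsp56 BSL78_09882 rose in both, and monocarboxylate transporter 6 BSL78_15659 fell in both. Independent lists would share 0.0529 risen and 0.00192 fallen genes. Simulated unchanged groups had at most 1 call to share and shared 0, so as many of their top-ranked genes as were called were compared instead. These shared from 1 to 6 genes (median 3.5) over 20 simulations with no change. The simulated genes were picked by rank rather than called, and were not matched to the 6 in size of change. The number 6 alone therefore cannot tell a shared response from sharing the controls. The 3 controls are too few to be split. The covariance of the log2 changes over all genes lay above the simulated value, 0.504 against 0.314 ± 0.00681 (SD of 20 simulations, in which genes varied independently), a difference of 0.19, and the correlation was 0.453 against 0.502 simulated. For 26 °C at 6 h and 48 h the covariance was 0.388 against 0.315 ± 0.00653, and for 48 h at 26 °C and 30 °C 0.419 against 0.314 ± 0.00619, with 0 shared calls in either. The 110 genes that rose at 30 °C had a median log2 change of 1.79 after 6 h at 26 °C, 97 of them above 0, and of 0.45 after 48 h, 83 above 0. With no change, the 110 top-ranked simulated genes had 85 to 104 above 0 after 6 h and 93 to 104 after 48 h, so these numbers do not speak for a shared response. Their simulated medians were 0.62 to 1.05 after 6 h, below the observed 1.79, and 0.74 to 1.09 after 48 h, above the observed 0.45, for genes with medians of 1.87 to 2.11 at 30 °C in place of 5.22. The 6 shared calls became 4, 3 and 4 without control animals 1, 2 and 3, and 4, 3 and 2 without 48 h animals 1, 2 and 3. They became 2 without 26 °C 6 h animal 2 or 3, and 3 and 27 without 30 °C animals 1 and 3.

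Set directly against 26 °C at 6 h, 30 °C raised some heat shock genes further. HSP26 BSL78_08844 was at 64929 ± 29218 FPKM against 1542 ± 2307 (SD, n = 3; log2 6.98, SE 1.17, adjusted p = 0.0351) and HSP26 BSL78_13663 at 89292 ± 66116 against 1293 ± 1265 (log2 6.60, SE 1.23, adjusted p = 0.049). HSP70 BSL78_02917 (6.53) and BAG3 BSL78_05946 (6.27, adjusted p = 0.0316) were the other heat shock genes past the test. HSP26 BSL78_13662 (5.49, adjusted p = 0.0644), HSP26 BSL78_13664 (6.16, adjusted p = 0.0783) and HSP70 BSL78_02892 (5.08, adjusted p = 0.141) were not past it. Of the 37 heat shock genes 27 were above 0. The list averaged 1.96 (adjusted p = 6.49e-07, adjusted p = 0.435 with an estimated correlation). Its mean was 1.09 with values rescaled to a common sum and 1.25 with quantile scaling. In it 4 rose over all genes and 13 adjusted over the list alone. The count of 4 was 0 without control animal 3, 26 °C 6 h animal 1 or 2, 48 h animal 2 or 3, or 30 °C animal 1 or 2. It was also 0 with either of those scalings, a pseudocount of 0.1, no filter or a fit of only the groups compared, and 2 with the animal number as a block. Without both 26 °C 6 h animal 1 and 30 °C animal 3 it was 1.

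Single genes outside the heat shock list also differed between 30 °C and 26 °C, among them 3 of 129 digestive enzymes and 1 of 195 lipid metabolism genes. Fatty acid-binding protein type 3-like BSL78_24333 was at 1073 ± 1274 FPKM against 0.672 ± 1.16, which is 3 reads (log2 7.99, SE 1.46, adjusted p = 0.0433; ratio 1180, counting interval 402 to 5710). Its 30 °C animals ran from 27.05 to 2493 FPKM, and the change was 6.60 without 30 °C animal 1 and 9.84 without animal 3. Another model of its name, BSL78_18483, was read in 48 h animal 3 and 30 °C animals 1 and 2 alone (971 reads). Presence or absence by animal was not tested for these models. Xanthine dehydrogenase (BSL78_27459, scaffold MRZV01001829.1, 91429 to 91596), which makes urate from purines, was at 1448 ± 1803 against 4.57 ± 7.92 FPKM (log2 7.91, SE 1.27, adjusted p = 0.0316), on a coding length of 168. Pancreatic lipase-related protein 3-like (BSL78_00488, scaffold MRZV01000009.1, 907669 to 913811), which splits dietary fat, stood at 132.8 ± 105.2 against 1.53 ± 2.65 FPKM (log2 5.92, SE 1.08, adjusted p = 0.0433). Alpha-amylase BSL78_20389 (4.69, SE 0.79, adjusted p = 0.0351) and the matrix protein tenascin (BSL78_03162, scaffold MRZV01000071.1, 15896 to 18174, 1 of 33 models; 5.42, SE 0.85, adjusted p = 0.0316) rose too. IMD-like BSL78_12555 fell to 0 reads, at least 36.9-fold (log2 -6.58, adjusted p = 0.000161). TIMELESS-interacting protein (BSL78_05914, scaffold MRZV01000151.1, 149641 to 153142), of replication forks, fell at least 7.12-fold (log2 -4.14, SE 0.73, adjusted p = 0.0415). Patronin (BSL78_01901, scaffold MRZV01000039.1, 386675 to 392640), which caps microtubules, fell at least 4.56-fold (log2 -3.69, SE 0.61, adjusted p = 0.0316). Perlecan-like BSL78_17848 (scaffold MRZV01000721.1, 26359 to 29953) fell at least 2.33-fold (log2 -3.04, SE 0.54, adjusted p = 0.0419). Galactosylceramide sulfotransferase BSL78_21866 fell from 73 reads to 1 (log2 -3.51, SE 0.63, adjusted p = 0.0423; ratio 47.2, counting interval 8.22 to 1890). These are differences between heat groups, not changes from control. In controls TIMELESS-interacting protein stood at 1.07 ± 1.09 FPKM, patronin at 5.72 ± 0.970 and perlecan-like at 1.59 ± 0.772. At 26 °C for 6 h they stood higher, at 22.8 ± 16.3, 13.5 ± 8.55 and 7.95 ± 4.11. Galactosylceramide sulfotransferase was at 32.4 ± 12.4 in controls and 12.9 ± 2.14 at 26 °C. Tenascin was at 20.2 ± 12.1 in controls and 2.65 ± 2.96 at 26 °C.

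As lists, digestive enzymes averaged 0.87 higher at 30 °C than at 26 °C (adjusted p = 0.000149, adjusted p = 0.435 with an estimated correlation; 3 risen over all genes, 7 risen and 1 fallen adjusted over the list alone). Extracellular matrix averaged 0.69 (adjusted p = 2.24e-05, adjusted p = 0.435 with an estimated correlation; 1 risen and 1 fallen, 3 and 1 adjusted over the list alone). Neuron markers averaged 0.54 (adjusted p = 0.00693, adjusted p = 0.514 with an estimated correlation). Rescaling to a common sum moved the median of all genes by -0.46, and relative to it these 3 lists averaged 0.62 (0.000363), 0.55 (1.01e-05) and 0.51 (0.000729). Another 6 passed, and in each bracket the last value is the rescaled mean relative to that median, with its adjusted p. They were ribosomal proteins (0.81, adjusted p = 3.94e-06, adjusted p = 0.514 with an estimated correlation; 0.27, 0.0728), oxidative phosphorylation (0.59, adjusted p = 0.000134, 0.514 estimated; 0.09, 0.608) and muscle markers (0.64, adjusted p = 0.000682, 0.435 estimated; 0.44, 0.0184). Lipid metabolism (0.51, adjusted p = 0.0174, 0.514 estimated; 0.40, 0.00632), innate immunity (0.56, adjusted p = 0.0179, 0.435 estimated; 0.40, 0.00571) and antioxidant enzymes (0.56, adjusted p = 0.021, 0.435 estimated; 0.28, 0.135) passed too. Ribosomal, respiratory and antioxidant calls were thus lost rescaled, as they were with quantile scaling (0.243, 0.441 and 0.111), where ribosomal proteins went the other way (-0.14). Lipid metabolism lost its call without 26 °C 6 h animals 1 (adjusted p = 0.0623) or 2 (0.0697) or 30 °C animals 1 (0.0583) or 2 (0.0666). Antioxidant enzymes lost theirs without 26 °C 6 h animal 1 (0.0623) or 30 °C animal 3 (0.11). Innate immunity lost its call without 26 °C 6 h animals 1 (0.113) or 3 (0.0546) or 30 °C animal 3 (0.113). Neuron markers lost theirs without 26 °C 6 h animal 3 (0.0704) or 30 °C animal 2 (0.21).

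In all, 37 genes were higher and 9 lower at 30 °C than at 26 °C after 6 h (2190 at an unadjusted p under 0.05), 18 and 6 of them named. IMD-like BSL78_12555 was the single named gene whose call held with any library left out. Of the 12 named calls, 7, 3 and 11 were lost without control animals 1 (adjusted p from 0.0588 to 0.0769), 2 (0.0563 to 0.0567) and 3 (0.0538 to 0.0612). Another 9, 11 and 3 were lost without 26 °C 6 h animals 1 (0.102 to 0.135), 2 (0.0745 to 0.144) and 3 (0.0555 to 0.079). The same held for 3, 10 and 9 without 48 h animals 1 (0.0562 to 0.0686), 2 (0.0565 to 0.0776) and 3 (0.0516 to 0.0789). It held for 11, 11 and 1 without 30 °C animals 1 (0.102 to 0.147), 2 (0.0811 to 0.146) and 3 (0.0544). The size of 8 of the 12 moved by over 1.5 times with a library left out. The 46 calls became 23, 27 and 5 without control animals 1, 2 and 3, and 6, 5 and 88 without 26 °C 6 h animals 1, 2 and 3. They became 13 and 14 without 48 h animals 2 and 3, and 4, 1 and 159 without 30 °C animals 1, 2 and 3. With values rescaled to a common sum, 0 rose and 1 fell, 0% risen in place of 80.4%.

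Between 6 h and 48 h at 26 °C, the heat shock list fell by 1.96 on the log2 scale (adjusted p = 1.2e-18, adjusted p = 0.35 with an estimated correlation), a sign kept under every scaling. Without controls labelled for each time, longer heat cannot be told apart from the passage of time in this comparison. In it 0 genes fell over all genes and 13 adjusted over the list alone. HSP26 BSL78_13662 was at 4172 ± 4477 FPKM after 6 h and 246 ± 177 after 48 h (SD, n = 3; log2 -3.78, SE 1.09, adjusted p = 0.49). HSP70 BSL78_02892 was at 2867 ± 3650 and 125 ± 127 (log2 -3.74, SE 1.33, adjusted p = 0.578). HSP26 BSL78_13663 (-3.09, adjusted p = 0.636), BSL78_13664 (-3.99, adjusted p = 0.545) and BSL78_08844 (-3.02, adjusted p = 0.627) were also lower without passing the test. The chaperonin list averaged -0.99 (adjusted p = 7.03e-05, adjusted p = 0.35 with an estimated correlation; 0 fallen over all genes and 3 adjusted over the list alone). Genes of DNA replication averaged 0.62 (adjusted p = 0.000333, adjusted p = 0.35 with an estimated correlation), and muscle markers 0.54 (adjusted p = 0.011, 0.597 estimated) higher after 48 h. Extracellular matrix averaged 0.40 (adjusted p = 0.0142, 0.597 estimated) and lipid metabolism 0.38 (adjusted p = 0.0181, 0.618 estimated) higher after 48 h. In these 4 lists 0 genes were called over all genes, and adjusted over the list alone 0 rose and 1 fell, a muscle marker against the direction of its list. Ribosomal proteins averaged -0.44 (adjusted p = 0.000333, adjusted p = 0.804 with an estimated correlation), and -0.40 relative to the median of all genes with values rescaled to a common sum (0.0114), but the call was lost with quantile scaling, at -0.01 from the median and with the test against other genes pointing upward (0.811).

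Single genes that fell between 6 h and 48 h at 26 °C numbered 2 by limma, with 0 risen (1313 at an unadjusted p under 0.05). They were IMD-like BSL78_12555, at least 70.2-fold lower (log2 -6.58, SE 0.53, adjusted p = 0.000161), and a hypothetical gene (BSL78_09881, log2 -3.81, adjusted p = 0.0419), named after its values were seen because it completes the count. The ribosomal call was lost without 26 °C 6 h animal 1 (adjusted p = 0.428) or 48 h animals 2 (0.075) or 3 (0.513). Lipid metabolism lost its call without 26 °C 6 h animals 1 (0.109) or 2 (0.143) or 48 h animal 3 (0.428). Extracellular matrix lost its call without 26 °C 6 h animals 2 (0.0659) or 3 (0.0576) or 48 h animal 2 (0.0584), and muscle markers without 26 °C 6 h animal 3 (0.0634) or 48 h animal 3 (0.14). The count of 2 was 1 without any of control animals 1 to 3, 48 h animal 1, 26 °C 6 h animals 1 and 3 or 30 °C animals 1 and 2. It was 4 without 26 °C 6 h animal 2 or 30 °C animal 3. Rescaled to a common sum, 2 rose and 2 fell, 50% risen in place of 0%. Over all 4 groups, 104 genes differed by the F test (1950 at an unadjusted p under 0.05). They numbered 53 and 55 without control animals 1 and 3, 54 and 62 without 48 h animals 2 and 3, and 34, 42 and 203 without 30 °C animals 1, 2 and 3.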

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

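Tests of the chance placement of neighbours, of shared names among neighbours, of depth for the number of genes detected and of a chance match with a group were chosen only after the result was seen. The results below are differences between heat groups that passed the test of the difference itself. Between 30 °C and 26 °C after 6 h, 46 genes differed, and between 48 h and 6 h at 26 °C, 2 genes differed. Fatty acid-binding protein type 3-like BSL78_24333 differed by 7.99 on the log2 scale between 30 °C and 26 °C. Xanthine dehydrogenase BSL78_27459 differed by 7.91. HSP26 BSL78_08844 differed by 6.98 and HSP26 BSL78_13663 by 6.60. Pancreatic lipase-related protein BSL78_00488 differed by 5.92, tenascin BSL78_03162 by 5.42 and alpha-amylase BSL78_20389 by 4.69. TIMELESS-interacting protein BSL78_05914 differed by -4.14, patronin BSL78_01901 by -3.69, galactosylceramide sulfotransferase BSL78_21866 by -3.51 and perlecan-like BSL78_17848 by -3.04. IMD-like BSL78_12555 differed by -6.58 both between 30 °C and 26 °C after 6 h and between 48 h and 6 h at 26 °C.

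The IMD-like model BSL78_12555 was read only in the 26 °C 6 h animals, 502 reads against 0 in the other 9 libraries. Depth is excluded, since at its lowest level in those animals 1062 reads would be due in the other 9, and so is a shift of reads to its other gene models, which gained 0.927% of its level in the other 9. Genes read in 3 libraries alone were rare, in 4.09% of the 220 sets of 3. Presence or absence by animal still cannot be told apart from a response: the bound of 5% set beforehand was wrong because 9 of the 10 such genes followed no group. A chance match of such a gene with a group may account for it (chance 16.8%), and reads from another organism cannot be told apart either, because 1 gene had this profile but foreign reads on genes the animals also express would not show, and a response to 6 h at 26 °C stays open.

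The splits of the 6 libraries of a comparison numbered 10, too few for a share under 0.05. For 26 °C at 6 h against control, 12 genes were called in the real split and at most 3 in another, a number as large in 1 of 10 splits. For 48 h against control 0 were called in the real split and at most 0 in others (10 of 10). For 30 °C against control they were 122 and at most 55 (1 of 10), for 30 °C against 26 °C 46 and at most 8 (1 of 10), and for 48 h against 6 h 2 and at most 2 (2 of 10). For lists past the preset-correlation test the real and highest other numbers were 5 and 8 (4 of 10), 4 and 6 (4 of 10), 9 and 10 (3 of 10), 10 and 13 (2 of 10) and 7 and 7 (3 of 10), in the same order. For the F test over all 12 libraries, 1 of 100 splits, the real one, gave as many as 104 genes, with 67 as the highest other. Chance is therefore unlikely there, though this share is the smallest that 100 splits can give. The F test does not settle the single comparisons.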

How the results depend on the processing

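Voom, the filter on reads, the covariate and the list test on rescaled and quantile-scaled values were tests chosen only after the result was seen. So was the fit without 26 °C 6 h animal 1 and 30 °C animal 3. Values are genes called in the order 26 °C 6 h, 26 °C 48 h and 30 °C against control, 30 °C against 26 °C, 48 h against 6 h, the F test and the overlap of 26 °C 6 h with 30 °C, which were 12, 0, 122, 46, 2, 104 and 6 as reported. The settings give the values that moved by over 1.5 times, and the cause was not tested unless given. In data simulated with the depth, spread and 3 animals of these groups 0 of 50 genes changed 4-fold were recovered, and these limits were not tested apart.

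Without a filter 26 °C 6 h gave 7, 30 °C against 26 °C 23 and the F test 56. With a mean of at least 5 FPKM 26 °C 6 h gave 25 and the overlap 12; fewer genes were tested. A pseudocount of 0.1 gave 4 for 48 h against 6 h. Rescaled to a common sum, the values were 6, 1, 51, 1, 4, 37 and an overlap of 2. Quantile scaling gave 29 for 30 °C against 26 °C and 1 for 48 h against 6 h, where it moved the median of all genes by -0.106. The rescaling to a common sum moved that median by -0.18, 0.12, -0.68, -0.46 and 0.29 in the 5 comparisons. It left 4 risen and 2 fallen genes for 26 °C 6 h (66.7% risen against 75%) and 1 and 0 for 26 °C 48 h. Median-of-ratios scaling moved no count by over 1.5 times, by construction, since the deposited values were already so scaled. Array weights gave 19 for 26 °C 6 h, 172 for the F test and an overlap of 13. A fit of only the groups compared, with fewer samples, gave 45 for 30 °C, 1 for 30 °C against 26 °C, 1 for 48 h against 6 h and an overlap of 3. Voom gave 19 for 26 °C 6 h, 8 for 30 °C against 26 °C and an overlap of 10. The number of genes detected as a covariate gave 41 for 26 °C 6 h, 1 for 48 h against 6 h and an overlap of 27. Without 26 °C 6 h animal 1 and 30 °C animal 3 the values were 66, 281, 99, 6, 210 and an overlap of 39, with 48 h against control at 0. The trend with robust variances, the log2 change of at least 1 and the filter on reads moved none of these counts by over 1.5 times.

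With the animal number as a replicate block, the values were 3, 1, 93, 17, 1, 63 and an overlap of 2. The labels give the groups the same numbers, but the values gave no clear sign that the numbers pair the animals. Of 18 same-numbered pairs, 1 had a correlation of deviations above 0.1 (range -0.18 to 0.146), and 2 of 12 libraries matched best with their own number. The median correlation was 0.0157 for same-numbered and -0.00891 for other pairs. With 3 animals per group such weak correlations cannot rule out pairing.

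Of fixed lists, 5, 4, 9, 10 and 7 passed as reported. With an estimated correlation 0, 0, 0, 0 and 0 passed. With fry for a common direction, which does not set a list against other genes, 1, 0, 1, 0 and 0 passed, the heat shock list in both. For change in either direction fry passed further lists, except at 48 h against control. Among them were mobile elements at 30 °C against control (adjusted p = 5.64e-05) and antioxidant enzymes at 30 °C against 26 °C (0.000138). A pseudocount of 0.1 left 1 at 48 h against control, rescaling to a common sum 2, and quantile scaling 4 of the 9 at 30 °C. By the direction of the test against other genes, oxidative phosphorylation at 30 °C reversed rescaled (adjusted p = 0.415) and with quantile scaling (0.0991; 8.16e-07 to 0.516 over alternatives). With quantile scaling ribosomal proteins reversed at 30 °C (0.0991; 3.96e-20 to 0.516), 30 °C against 26 °C (0.243; 4.25e-10 to 0.514) and 48 h against 6 h (0.811; 2.3e-16 to 0.811). Over its alternatives, fry included, the adjusted p of the heat shock list ran from 1.93e-37 to 0.125 at 26 °C 6 h, 5.11e-14 to 0.876 (by fry) at 48 h and 1.94e-52 to 0.0697 at 30 °C.

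Leaving out each library in turn gave 4 to 37 genes for 26 °C 6 h, 0 to 1 for 48 h, and 52 to 258 for 30 °C. It gave 1 to 159 for 30 °C against 26 °C, 1 to 4 for 48 h against 6 h and 34 to 203 for the F test. The overlap of 26 °C 6 h with 30 °C ran from 2 to 27 and the other overlaps from 0 to 1. Lists past the test ran from 4 to 9, 2 to 6, 7 to 9, 7 to 10 and 4 to 8. In the test against other genes, the direction of ribosomal proteins reversed at 26 °C 6 h without control animal 3 (adjusted p = 0.0157, with 6.55e-07 to 0.742 with each library left out). It reversed at 48 h without control animal 1 (0.192) or 48 h animal 3 (0.747; 2.54e-13 to 0.799 with each left out). Over the 39 calls of named genes, 387 fits with another setting kept the call and 153 lost it. Another 286 fits with a library left out kept it and 182 lost it, with 0 reversed in both.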

Other observations

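Tests of the chance placement of neighbours, of shared names among neighbours and of depth for the number of genes detected were chosen only after the result was seen, and the genes of the next paragraph were chosen after their values were seen. Among the 110 genes that rose at 30 °C, 32 were named genes outside the lists, and those below were picked by eye from them, with no list or test behind the choice. The dnaJ-like models BSL78_01137 (log2 9.12) and BSL78_01136 (8.52), co-chaperones of HSP70, rose, as did a model of the Hop Tpr2a domain (BSL78_07969, 6.34), which links HSP70 and HSP90, CHORD-domain protein (BSL78_06083, 4.56) and AN1-type zinc finger protein 2B (BSL78_15558, 4.36). Sequestosome-1 (BSL78_15318), which carries ubiquitinated protein to autophagy, rose from 67.8 ± 11.8 to 1894 ± 994 FPKM (SD, n = 3; log2 4.68, adjusted p = 0.00898). Calcium-binding calumenin rose in BSL78_14051 (5.98), BSL78_06654 (3.72) and BSL78_06653 (3.11), and the signal recognition particle receptor in BSL78_12417 (6.04), BSL78_03887 (5.93) and BSL78_12418 (4.89). Some of these models are neighbours on the same strand. They are BSL78_01136 and BSL78_01137 (38 bp apart), BSL78_06653 and BSL78_06654 (841 bp) and BSL78_12417 and BSL78_12418 (688 bp). The Hop model BSL78_07969 lies 2181 bp from stress-induced phosphoprotein 1 BSL78_07970. Such neighbours may not be separate genes, which was not tested. The transcription factor Klf1/2/4 (BSL78_14878) rose from 92.6 ± 71.2 to 672 ± 86.6 FPKM (log2 3.10), gamma-glutamylcyclotransferase-like (BSL78_04988), of glutathione turnover, by 5.51, and cytochrome P450 1A1-like (BSL78_19647) by 2.49.

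The genes that rose at 30 °C lay next to one another on the scaffolds, with 21 neighbouring pairs among 110 genes, against a mean of 0.42 and at most 5 in 10000 random sets (permutation p = 1e-04, the smallest they can give), which excludes chance placement. Reads running past the end of an induced gene are excluded as the single source of all pairs, but not as the source of some. In same-strand pairs the downstream gene was the lower in 33.3% (6 of 18, interval 13.3 to 59), where such reads need nearly all. By themselves head to head pairs, 9.52% (interval 1.17 to 30.4, 21.7% among all neighbours), left such reads open as a cause. Copies sharing reads cannot be told apart from separate induction, because 60% of the 10 pairs with names carried the same name (interval 26.2 to 87.8), as the HSP26 models BSL78_13662 and BSL78_13663 do. A candidate explanation not tested is a gene broken over neighbouring models. The pairs had a median gap of 854 bp, against 7137 bp among all neighbouring tested genes, and 85.7% against 53.3% lay on the same strand. Hypothetical genes were 17 of the 40 in such pairs and 52 of all 110 risen genes. Shared induction by heat stays open as a hypothesis.

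Fewer genes were detected at equal depth at 30 °C than in controls, 13894 ± 1236 against 16910 ± 1644 (SD, n = 3 each), with 14666 ± 1993 after 6 h at 26 °C. Depth is excluded, since the difference of 3016 was measured with every library thinned to 1700000 reads and exceeds the larger SD of 1644. A few heat shock genes taking the reads cannot be told apart from a wider loss: at 1200000 reads the difference was 3240 with all genes and 2261 without the heat shock list and the 10 most read genes, so 69.8% was left. The groups then overlapped, and the 980 recovered lay below the 1620 that such a cause needs by less than the SD of 667 between libraries. Library complexity was not tested, and a difference between heated and control guts may remain, where the exact permutation p of 0.1 is the smallest 3 animals against 3 can give.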
